A study of Aegilops tauschii and Oryza sativa and Triticum aestivum with 22 samples.

How the data were processed

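Poly(A) RNA-seq libraries from cereal plants were analysed, 22 in all, from 7 species and 11 groups of 2 libraries. Per the labels' protocols, poly(A) RNA was selected from total RNA with oligo(dT) beads, made into libraries with a directional kit and sequenced on an Illumina NovaSeq instrument. The groups were above-ground seedlings of rice cultivars Jap and ZH11, maize B73, barley Morex and rye Weining at 9 days, leaf, root and embryo of Aegilops tauschii AL8-78, embryo of Triticum urartu G1812, and leaf and root of bread wheat Chinese Spring. Roots and leaves were from 9-day plants and embryos were immature, 14 days after anthesis. Groups and replicate numbers were taken from the sample titles. What the word mock in the wheat titles refers to is not given in the sources used here. Nothing in the labels states whether replicates came from separate plants, so p-values measure only the spread between libraries, which may be technical.

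The submitters' processing notes list fastp 0.20.1, HISAT2 2.1.0, SAMtools 1.16.1 and StringTie 2.1.7, with no settings. The only genome build in those notes is B73 RefGen_v4, a maize build; the builds of the other species are not given in the sources used here, and neither is the strand setting of the counting. Per the file headers, each library has a table of genes with coverage, FPKM and TPM. Coverage was deposited as mean read depth per base, not scaled for library size. FPKM was deposited as scaled for gene length and library size, and TPM was deposited as a constant times FPKM within each library. In units of 1000 TPM, the deposited values of listed genes summed to 813 to 966 per library outside rye, short of the full total. Such scaling to a fixed total means that a rise of a few abundant genes lowers the TPM of all others.

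Rye differed. Each rye gene was listed 8 times, and the ratio of coverage to FPKM was near constant within a chromosome, with 98.5% to 99.8% of values within 1% of it. It differed between chromosomes, by 12.1-fold between the largest and smallest. The deposited rye FPKM and TPM were therefore treated as a score scaled separately for each chromosome. The deposited rye TPM summed to 7071150 and 7084260 in the libraries. Rye TPM used here was recomputed from the deposited coverage over all chromosomes.

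Depth was taken from the constant that links coverage and FPKM, which gives the bases counted by the quantifier. It ranged from 3.61 to 14.1 Gb per library. Genes whose coverage times locus length was a whole number of bases were taken as single-exon genes. Their fragments were counted at an assumed 300 bases each, and the squared difference between replicates was set against sampling noise. The mean ratio was 1.10 to 1.72 in 10 groups. In T. urartu embryo it was 1.03, with a chi-square p of 0.161. In these genes those libraries differed by no more than the sampling noise, and they were counted as 1 sample without an SD.

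Rows of a gene ID were summed. Genes with TPM of at least 1 in at least 2 libraries of a fit were tested with limma 3.58.1 in R 4.3.3 on log2(TPM + 1), with eBayes and an intensity trend, two-sided, and called at a Benjamini-Hochberg adjusted p under 0.05. A fold change on the log2(TPM + 1) scale understates the change of genes with low TPM. Rice and wheat fits held 4 libraries each, and the 3 Ae. tauschii comparisons came from 1 fit of 6 libraries, so they share libraries. A permutation test of 2 libraries against 2 cannot give a two-sided p below 0.333, so values of single measures are given without a call. Libraries of different species were set side by side without a test, since their annotations differ. Other steps used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

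The test was checked on simulated data. Each library was drawn around the gene's mean over all libraries of the fit, with the gene's moderated spread. At each fold 50 genes were changed, and all others were left unchanged. The changed genes were drawn only from genes with a mean TPM well above the filter of the test. Recovery of genes near the filter was not simulated, so the percentages below do not cover them. In the rice fit of 20316 genes, 66% of 1.25-fold, 96% of 1.5-fold and 100% of 2-fold changes were recovered, and 30 unchanged genes were called. In the Ae. tauschii root and leaf fit of 21263 genes, recovery was 0%, 54% and 96% at the same folds, with 6 unchanged genes called. In the wheat fit of 47219 genes it was 14%, 86% and 100%, with 24 unchanged genes called. These gene numbers are those of the simulated fits. The real fits called 47.6% of genes in rice, 84.9% in Ae. tauschii root minus leaf and 82.6% in wheat. With so many calls, larger p-values pass the Benjamini-Hochberg threshold. Recovery and false calls of the real fits may therefore differ from the simulated values.

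The files do not pair most gene IDs with names. Names were given in the files for 1827 Ae. tauschii loci, all noncoding RNAs, and for 3514 barley loci. The table of RefSeq names supplied with the data, for assembly Aet v6.0, matched 0 of the IDs. For that reason all 22 gene lists fixed before the data were examined were void, as 0 of them had 3 tested members in a comparison, and no gene set test of the lists or comparison of list levels between embryos was run. Genes to be named were fixed by a rule before the data were examined. For each comparison these were the genes with the largest log2 fold change in each direction among called genes with a mean TPM of at least 20 in the higher group and no overlap between the libraries of the groups. Only 2 IDs per direction are given, because no names were known. For seedlings without a comparison the rule was the 5 genes with the highest mean TPM, where they had names, and it named 0 genes. Named noncoding loci and named barley genes fall outside these rules and were chosen after their values were seen.

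Positions are those of the files. In wheat and barley the files give positions within part 1 or part 2 of a chromosome. Chromosome length was taken as the highest gene end. Genes in the outer 20% at each end were called distal and the others proximal, and the groups were compared with Fisher's exact test. Neighbouring rice calls were compared with 10000 shuffles of the calls within chromosomes, one-sided. These tests and the subgenome tests were fixed before the data were examined. Windows of 1 Mb, runs of neighbouring genes, 8-fold distal calls, noncoding classes, and shares by chromosome number were chosen after the data were seen. Windows with at least 10 tested genes were tested with a one-sided binomial test. A run was at least 4 neighbouring tested genes called in the same direction with at least 8-fold change, or 2-fold in rice, set against 1000 shuffles, one-sided, for which 0.001 is the smallest p. Tests across genes treat genes as independent, which neighbouring and duplicated genes are not. Reads shared between homoeologous, duplicated or overlapping genes could not be traced from these files, so values of single copies are uncertain where copies are near identical.

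Alternatives were another pseudocount, no filter and a filter at TPM 5, FPKM in place of TPM, quantile normalization, median-ratio scaling, TPM rescaled over nuclear genes, no intensity trend, a minimum 2-fold change, each replicate left out, and the replicate number as a block. The fit of only the 4 libraries compared was also tried in Ae. tauschii.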

Results

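The data were TPM values of annotated genes in 22 poly(A) RNA libraries of cereals. Rice was represented by seedlings of cultivars Jap and ZH11, and maize, barley and rye by seedlings of B73, Morex and Weining. Ae. tauschii, a wild diploid grass related to the D subgenome of bread wheat, was represented by leaf, root and embryo. T. urartu, a wild diploid related to the A subgenome, was represented by embryo, and bread wheat, a hexaploid with subgenomes A, B and D, by leaf and root. Each of the 11 groups held 2 libraries. The series title sets these libraries beside a study of enhancer RNAs; the chromatin-bound RNA of that study was not analysed here.

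Depth per library, for replicates 1 and 2, was 5.84 and 10.04 Gb in rice Jap, 6.73 and 10.7 Gb in rice ZH11, 7.24 and 10.6 Gb in maize, 7.80 and 12.3 Gb in barley, and 4.70 and 9.55 Gb in rye. In Ae. tauschii it was 14.1 and 4.92 Gb in embryo, 3.61 and 8.07 Gb in leaf, and 12.2 and 4.01 Gb in root. It was 11.3 and 5.98 Gb in T. urartu embryo, 8.58 and 7.01 Gb in wheat leaf, and 5.99 and 6.46 Gb in wheat root. Replicates correlated with Pearson r of 0.994 to 0.998 across genes on the log2(TPM + 1) scale; genes are not independent replicates.

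More genes passed TPM 1 in roots than in leaves, and root RNA was spread over more of them. In Ae. tauschii, 20639.5 ± 43.1 genes (SD, n = 2) had TPM of at least 1 in root, against 18468.5 ± 23.3 in embryo and 17260.0 ± 9.90 in leaf. The 100 most abundant genes held 23.5% ± 0.0157 of TPM in root, 37.4% ± 1.12 in embryo and 45.9% ± 0.129 in leaf. In wheat, 48500.0 ± 229 genes passed TPM 1 in root and 39799 ± 66.5 in leaf, and the 100 most abundant genes held 16.7% ± 0.282 and 35.5% ± 0.155 of TPM (n = 2 each). Every root library lay above every leaf library of its species in the number of genes, but 2 libraries against 2 cannot reach p = 0.05 in an exact test. The difference between root and leaf was 3379.5 genes in Ae. tauschii and 8701 in wheat as deposited, and 1881.5 and 4213.5 with median-ratio scaling. T. urartu embryo, counted as 1 sample, had 17211.5 genes at TPM 1. Seedlings had 20011.5 ± 60.1 in rice Jap, 20315 ± 15.6 in rice ZH11, 20143 ± 4.24 in maize, 17478.5 ± 41.7 in barley and 19598.5 ± 2.12 in rye, which were not compared across annotations.

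**Figure D1:**
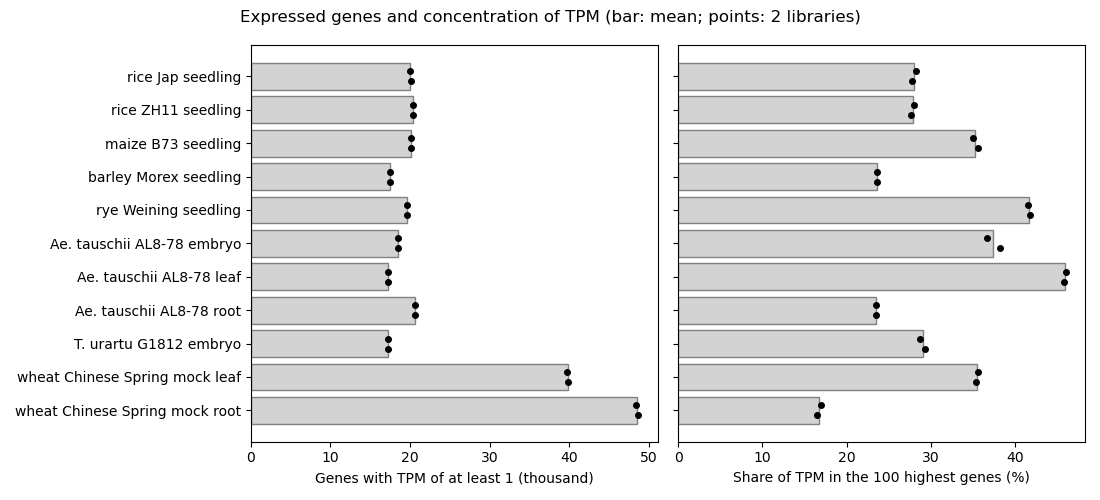
Genes with TPM of at least 1 (left, in units of 1000 genes) and percent of TPM held by the 100 most abundant genes of each library (right) in the 11 groups. Bars are means and points are the 2 libraries of a group; in Ae. tauschii the leaf bars are at 17260.0 genes and 45.9%, the root bars at 20639.5 genes and 23.5%.

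The genes named by rule in seedlings of rice cultivars Jap and ZH11 were abundant in one cultivar and near 0 in the other, which the rule favours. LOC_Os08g14350 (chromosome 8, 8605007 to 8605717) was at 314.5 ± 7.23 TPM in ZH11 and 0.404 ± 0.0743 in Jap, a log2 fold change of 7.81 (SE 0.0709, limma adjusted p = 3.79e-09). LOC_Os05g48710 (chromosome 5, 27920719 to 27923744) was at 246 ± 5.98 TPM in ZH11 and 0.351 ± 0.0559 in Jap, a log2 fold change of 7.52 (SE 0.0724, limma adjusted p = 3.79e-09). In the other direction, LOC_Os09g32169 (chromosome 9, 19195347 to 19196161) was at 0.195 ± 0.111 TPM in ZH11 and 505 ± 23.7 in Jap, a log2 fold change of -8.73 (SE 0.0823, limma adjusted p = 3.79e-09). LOC_Os06g19095 (chromosome 6, 10865395 to 10867828) was at 0.170 ± 0.00373 TPM in ZH11 and 269 ± 9.62 in Jap, a log2 fold change of -7.85 (SE 0.0711, limma adjusted p = 3.79e-09; n = 2 per group for all 4 genes).

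Of 20841 rice genes tested, 9915 were called, 5133 higher and 4782 lower in ZH11. Most differences were small: 1827 called genes differed at least 2-fold, 1170 higher and 657 lower in ZH11, and 202 at least 8-fold. With the filter applied again without Jap replicate 1 or 2, genes at least 2-fold lower in ZH11 numbered 397 and 378, and those of at least 8-fold 112 and 116. That drop follows from the filter, since genes near 0 in ZH11 then cannot reach TPM 1 in 2 libraries and are not tested. Without a ZH11 replicate, genes at least 2-fold higher in ZH11 became fewer in the same way. Among the genes tested, 111 were listed at 0 in both ZH11 libraries with TPM of at least 1 in both Jap libraries, and 48 showed the converse. With at least 20 TPM in the expressing cultivar, the numbers were 10 and 0. The share of all calls higher in ZH11 was 51.8% as deposited and under 50% in 4 alternatives. It was 47.3% with quantile normalization, 49.9% with the filter at TPM 5, and 49.8% and 48.7% without ZH11 replicates 1 and 2 when the filter was applied again.

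Large cultivar differences were spread unevenly along rice chromosomes. Genes of at least 2-fold made up 15.6% of tested genes on chromosome 11, 12.4% on chromosome 6 and 6.24% on chromosome 3, against 8.76% over all chromosomes. The densest window, at 27 to 28 Mb of chromosome 11, held 23 such genes among 35 tested, 18 of them lower in ZH11 (adjusted p = 5.22e-14). Next were 6 to 7 Mb of chromosome 12, with 21 of 34 (adjusted p = 3.48e-12), and 28 to 29 Mb of chromosome 11, with 22 of 50 (adjusted p = 5.24e-09). In all, 23 of 374 windows held an excess; they contained 16.7% of the genes of at least 2-fold and 4.15% of tested genes. In 20 of the 23 most of these genes were lower in ZH11 and in 2 most were higher, whereas over all chromosomes 1170 were higher and 657 lower.

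Neighbouring genes also differed together in runs, some of them outside the windows with an excess. There were 24 runs of at least 4 neighbours, 17 lower and 7 higher in ZH11, holding 128 genes; shuffles gave a mean of 0.264 runs and at most 3. The longest was a run of 10 genes on chromosome 9 (11374271 to 11556180), whose TPM summed to 243 ± 0.446 in Jap and 1.29 ± 0.704 in ZH11. A run of 9 genes on chromosome 11 (27683640 to 27785982) summed to 116 ± 0.143 TPM in Jap and 6.12 ± 0.655 in ZH11. The longest run higher in ZH11 was of 8 genes on chromosome 7 (1943386 to 1972039), at 73.03 ± 1.38 TPM in ZH11 and 25.7 ± 1.504 in Jap, and 4 genes on chromosome 2 (26163059 to 26186920), in a window without an excess (adjusted p = 0.718), summed to 1010.5 ± 14.1 and 36.5 ± 2.59 TPM. Both neighbours were called in 24.0% of neighbouring pairs, against a shuffled mean of 22.7% and highest of 23.4% (permutation p = 0.0001, the smallest that 10000 shuffles can give). For genes of at least 2-fold the share was 2.104% against a shuffled mean of 0.821% (permutation p = 0.0001). Neither the cultivar of the reference nor any more on Jap than its label is given in the sources used here, so which cultivar lies closer to the reference is unknown.

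**Figure D2:**
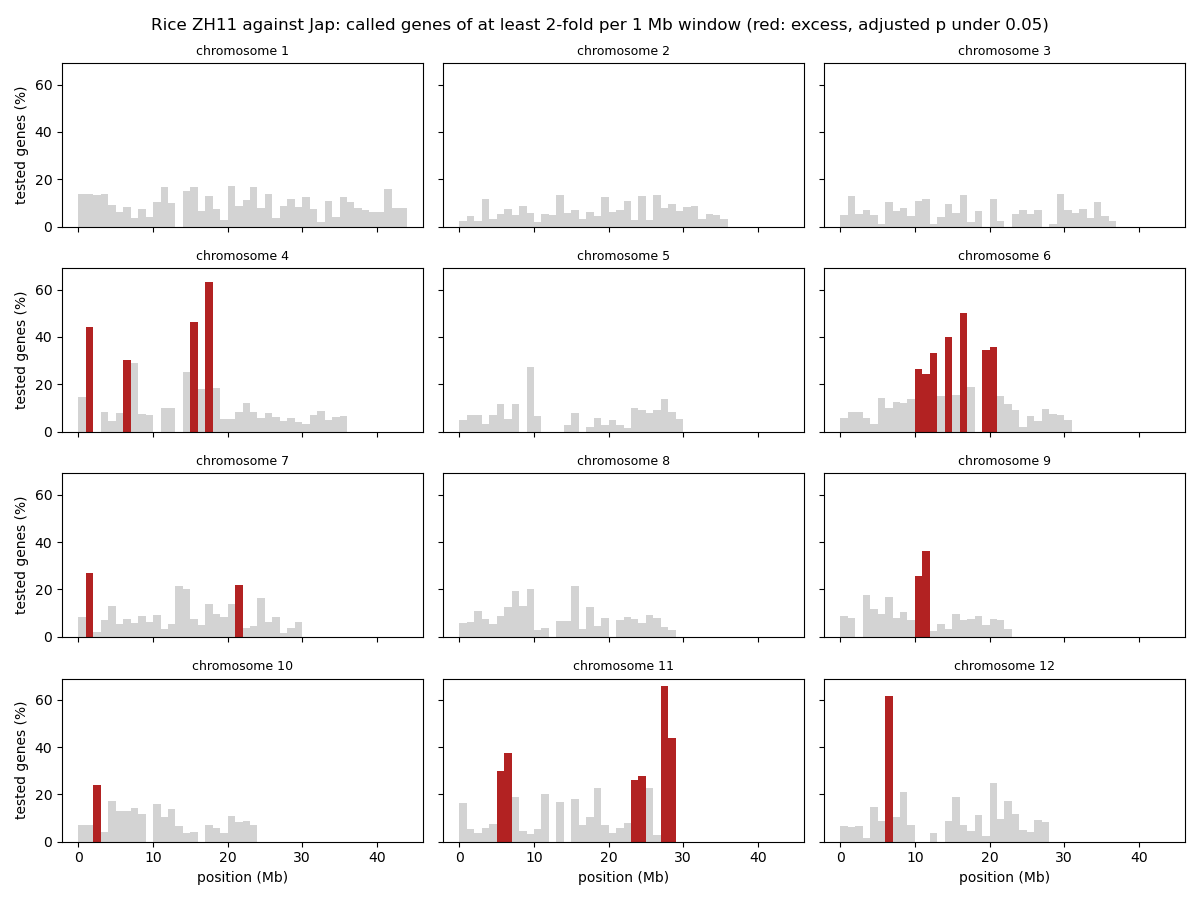
Percent of tested genes called with at least 2-fold difference between ZH11 and Jap in 1 Mb windows (y axis) along the 12 rice chromosomes (x axis, Mb); windows have at least 10 tested genes and red marks the 23 with an excess. The highest bar is 65.7%, on chromosome 11.

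Root and leaf of Ae. tauschii differed in most genes. AET4Gv20012800 (chromosome 4D, 2519963 to 2524271) was at 2399 ± 22.1 TPM in root and 0.0740 ± 0.00296 in leaf, a log2 fold change of 11.13 (SE 0.0656, limma adjusted p = 3.24e-08). AET1Gv20559900 (chromosome 1D, 321106265 to 321135919) was at 1898 and 1878 TPM in the root libraries and listed at 0 in both leaf libraries (limma adjusted p = 3.73e-08). AET4Gv20287100 (chromosome 4D, 125167025 to 125174362) was at 4.62 ± 1.38 TPM in root and 21159 ± 1245 in leaf, a log2 fold change of -11.90 (SE 0.197, limma adjusted p = 1.38e-07). AET5Gv20809800 (chromosome 5D, 446476868 to 446478373) was at 2.37 ± 0.616 TPM in root and 9905 ± 381 in leaf, a log2 fold change of -11.53 (SE 0.123, limma adjusted p = 6.39e-08; n = 2 per tissue).

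Of 23650 genes tested, 20073 were called, 14967 higher and 5106 lower in root; 13719 differed at least 2-fold and 3652 at least 8-fold. At least 20 TPM in both root libraries was found for 329 genes listed at 0 in both leaf libraries, and the converse for 45. Of the genes with at least 8-fold change, 2304 were higher and 1348 lower in root. Neighbours among them formed 28 runs, against a shuffled mean of 2.21 (permutation p = 0.001, the smallest that 1000 shuffles can give). Of the runs 27 were higher in root, the side of most such genes, and their direction was not tested. The longest was 8 genes on chromosome 2D (542349829 to 543250729), summing to 408 ± 26.8 TPM in root and 3.25 ± 0.329 in leaf. The only run higher in leaf was 6 genes on chromosome 5D (535317039 to 536014143), at 182 ± 1.18 TPM in leaf and 6.77 ± 1.09 in root. The share of calls higher in root was 74.6% with TPM as deposited, 57.4% with median-ratio scaling and 53.7% with quantile normalization. The median log2 difference of all genes was 0.78 as deposited and 0.17 with median-ratio scaling, so small differences in either direction are relative to the scaling. At 2-fold, 6695 genes were higher in root with median-ratio scaling, and 6159 higher and 5382 lower with quantile normalization, against 10164 and 3555 as deposited.

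The genes with the largest rise from leaf to embryo of Ae. tauschii were very abundant in embryo and almost silent in leaf. The naming rule favours such genes. The 100 most abundant genes held 37.4% of TPM in embryo and 45.9% in leaf. The 10 most abundant held 17.7% ± 0.632 in embryo, 18.4% ± 0.167 in leaf and 7.48% ± 0.0242 in root. The single most abundant gene held 4.23% in embryo and 2.81% in leaf. The neighbouring genes AET4Gv20027600 (chromosome 4D, 6213941 to 6217209) and AET4Gv20027500 (6201132 to 6203822) held 4.23% and 3.59% of embryo TPM. AET4Gv20027600 was at 35929.7 ± 1108 TPM in embryo and 0.0257 ± 0.0364 in leaf, a log2 fold change of 15.10 (SE 0.297, limma adjusted p = 2.08e-07). AET4Gv20027500 was at 30509.5 ± 1326 TPM and 0.116 ± 3.39e-05, a log2 fold change of 14.74 (SE 0.284, limma adjusted p = 1.93e-07). In the other direction, AET5Gv20989600 (chromosome 5D, 498701623 to 498710268) was at 0.549 ± 0.409 TPM in embryo and 5664 ± 13.4 in leaf, a log2 fold change of -11.86 (SE 0.265, limma adjusted p = 3.18e-07). AET7Gv20671300 (chromosome 7D, 266689889 to 266691057) was at 4.84 ± 0.809 TPM in embryo and 15725 ± 712 in leaf, a log2 fold change of -11.40 (SE 0.127, limma adjusted p = 4.14e-08; n = 2 per tissue).

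Embryo and leaf differed in 19427 of 23650 genes, 12473 higher and 6954 lower in embryo; 13582 differed at least 2-fold and 3671 at least 8-fold. At least 20 TPM in both embryo libraries was found for 258 genes listed at 0 in both leaf libraries, and the converse for 104. There were 8 runs of neighbouring genes with at least 8-fold change, 6 of them higher in embryo, against a shuffled mean of 1.56 (permutation p = 0.001). In one, 5 genes on chromosome 1D (4813841 to 4935237) summed to 309 ± 21.7 TPM in embryo and were listed at 0 in both leaf libraries. In another, 6 genes on chromosome 3D (71560800 to 72177181) summed to 632 ± 6.14 TPM in embryo and 0.602 ± 0.348 in leaf. The share of calls higher in embryo was 64.2% with TPM as deposited, 49.5% with median-ratio scaling and 55.9% with quantile normalization, and the median log2 difference of all genes was 0.44 as deposited and 0 with median-ratio scaling. Under median-ratio scaling the majority turned also at 2-fold, with 5630 higher and 6538 lower in embryo.

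Embryo and root of Ae. tauschii each had abundant genes that were near 0 in the other tissue. In embryo the pair on chromosome 4D was most abundant, while in root AET4Gv20027600 was at 0.945 ± 0.894 TPM (log2 fold change 14.25, SE 0.297, limma adjusted p = 3.32e-07) and AET4Gv20027500 at 1.05 ± 0.903 (log2 fold change 13.94, SE 0.284, limma adjusted p = 3.07e-07). AET4Gv20870300 (chromosome 4D, 521273908 to 521275449) was at 0.442 ± 0.0648 TPM in embryo and 8898 ± 169 in root, a log2 fold change of -12.59 (SE 0.0473, limma adjusted p = 1.94e-08). AET6Gv20403200 (chromosome 6D, 145153352 to 145328570) was at 0.912 ± 0.418 TPM in embryo and 11338 ± 134 in root, a log2 fold change of -12.55 (SE 0.178, limma adjusted p = 1.20e-07; n = 2 per tissue).

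Of 23650 genes, 18287 were called, 8289 higher and 9998 lower in embryo. Among the 10495 of at least 2-fold, 3749 were higher and 6746 lower in embryo; 2905 differed at least 8-fold. At least 20 TPM in both root libraries was found for 226 genes listed at 0 in both embryo libraries, and the converse for 63. Of the genes with at least 8-fold change, 697 were higher and 2208 lower in embryo. Neighbours among them formed 30 runs, against a shuffled mean of 1.72 (permutation p = 0.001). Of the runs 27 were lower in embryo, the side of most such genes, and their direction was not tested. One held 6 genes on chromosome 6D (2859273 to 3236314), at 0.934 ± 0.611 TPM in embryo and 687 ± 11.5 in root, and another 6 genes on chromosome 1D (488660879 to 488770620), at 0.0216 ± 0.0305 and 591 ± 10.2 TPM. The share of all calls higher in embryo was 45.3% as deposited, 46.9% with median-ratio scaling and 58.2% with quantile normalization. Under quantile normalization the majority turned also at 2-fold, with 6070 higher and 5274 lower in embryo. With the filter applied again, the share of all calls higher in embryo was 51.4% without root replicate 1 and 50.8% without root replicate 2.

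Noncoding RNA loci were the only named genes of Ae. tauschii. Loci of small nucleolar RNAs (snoRNAs), which guide chemical modification of ribosomal RNA, summed to 177 ± 9.72 TPM in leaf, 781 ± 12.9 in root and 848 ± 66.6 in embryo (n = 2 each). The libraries were selected for poly(A), so how far values at noncoding loci reflect the mature RNAs is unknown. Of 198 tested snoRNA loci, 144 were higher and 2 lower in root than leaf, 143 were higher and 1 lower in embryo than leaf, and 39 were higher and 27 lower in embryo than root. Their median log2 difference was 1.30 in root minus leaf and 1.28 in embryo minus leaf, or 0.94 and 0.95 with median-ratio scaling. Of these loci, 103 lay inside or across other listed genes and 95 outside them. Their median log2 differences in root minus leaf were 1.28 and 1.32. Against all other genes, camera gave an adjusted p of 0.00147 for embryo minus leaf with the preset correlation, and an adjusted p = 0.366 with an estimated correlation. For root minus leaf the adjusted p was 0.155, and 0.497 with an estimated correlation, so a rise of the class beyond that of other genes did not pass the test there.

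Many snoRNA loci lie in clusters. A cluster of 8 on chromosome 1D (443665482 to 443667968) summed to 81.8 ± 9.27 TPM in embryo, 16.2 ± 1.13 in leaf and 90.6 ± 0.00504 in root, with 8 of 8 loci called higher in root than leaf. A cluster of 11 on chromosome 5D (18572521 to 18576356) was at 40.4 ± 8.87, 7.98 ± 3.32 and 39.6 ± 0.190 TPM in the same order. In 53 of 62 clusters, 20 of them single loci, root exceeded leaf. The snoRNA snoR28 (chromosome 7D, 103786385 to 103786462) was at 68.5 ± 3.06 TPM in embryo, 0.772 ± 0.872 in leaf and 31.3 ± 6.32 in root. Its locus overlaps another gene, and the counting of overlapping genes is not given in the sources used here.

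Other noncoding classes with tested loci included spliceosomal RNAs and microRNA precursors. Spliceosomal loci summed to 67.7 ± 1.60 TPM in root, 47.8 ± 0.984 in leaf and 5.81 ± 0.316 in embryo, and 6 of 6 tested loci were lower in embryo than root. Against all other genes, camera did not pass for them in embryo minus root (adjusted p = 0.237 with the preset correlation, adjusted p = 0.676 with an estimated correlation). A U5 locus on chromosome 3D (554679970 to 554680080) was at 32.6 ± 0.589 TPM in root and listed at 0 in both leaf libraries, and a U1 locus on chromosome 1D (300721671 to 300721831) was at 29.9 ± 5.21 TPM in leaf, 14.5 ± 1.37 in root and 0.339 ± 0.0162 in embryo. Precursors of microRNAs summed to 35.7 ± 7.15 TPM in leaf, 19.05 ± 0.678 in root and 9.22 ± 1.18 in embryo; 6 of 11 tested were lower and 1 higher in root than leaf (camera adjusted p = 0.0201 with the preset correlation, adjusted p = 0.497 with an estimated correlation). A MIR169_2 locus on chromosome 2D (630634535 to 630634650) was at 10.9 ± 1.11 TPM in leaf and 2.00 ± 1.40 in root, and listed at 0 in both embryo libraries. The U5, U1 and MIR169_2 loci named here also overlap other genes.

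**Figure D3:**
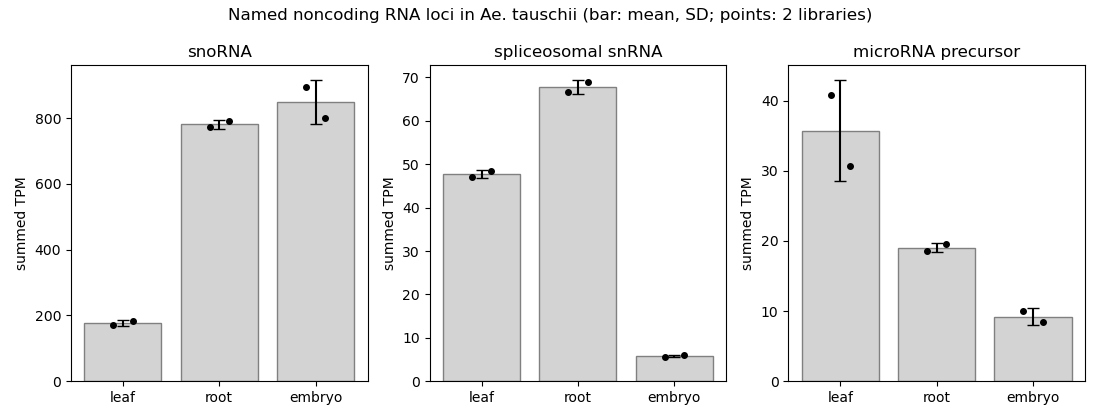
Summed TPM of snoRNA, spliceosomal RNA and microRNA precursor loci (y axes) in leaf, root and embryo of Ae. tauschii. Bars are means with SD and points are the 2 libraries of each tissue; snoRNA loci sum to 177 TPM in leaf, 781 in root and 848 in embryo.

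In wheat, the genes with the largest difference between root and leaf in each direction had neighbours that differed too. TraesCS1D02G265900 (chromosome 1D part 1, 361844934 to 361845327) was at 8807 ± 158 TPM in root and 0.911 ± 0.434 in leaf, a log2 fold change of 12.19 (SE 0.142, limma adjusted p = 3.50e-08). Its neighbour TraesCS1D02G266000 (361907486 to 361908378) was at 4311 ± 121 TPM in root and 1.84 ± 0.575 in leaf, a log2 fold change of 10.58 (SE 0.130, limma adjusted p = 3.95e-08). In the other direction, TraesCS2A02G066800 (chromosome 2A part 1, 30047902 to 30049124) was at 2.09 ± 0.811 TPM in root and 3603 ± 39.2 in leaf, a log2 fold change of -10.21 (SE 0.163, limma adjusted p = 9.13e-08). The adjacent TraesCS2A02G066700 (30020633 to 30021500) was at 0.636 ± 0.255 TPM in root and 1819.8 ± 29.5 in leaf, a log2 fold change of -10.13 (SE 0.107, limma adjusted p = 2.62e-08; n = 2 per tissue).

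These genes belonged to runs seen on several subgenomes. In root, 4 neighbouring genes on chromosome 1D part 1 (361802498 to 361915200) summed to 20504 ± 343 TPM, against 109.9 ± 0.698 in leaf. A further 4 on chromosome 1A part 1 (461337578 to 461373455) summed to 18017 ± 105 TPM in root and 458 ± 5.03 in leaf. In leaf, 7 genes on chromosome 2A part 1 (30020633 to 30127338) summed to 8592 ± 45.3 TPM, 6 genes on 2B part 1 (44190500 to 44361961) to 6809 ± 30.8, and 6 genes on 2D part 1 (27853295 to 27902757) to 7318 ± 87.4. The same runs were at 5.60 ± 0.764, 17.6 ± 1.89 and 9.59 ± 1.37 TPM in root. On chromosome 5B part 2 (186962980 to 187025129), 4 genes summed to 3439 ± 14.4 TPM in leaf and 2.22 ± 0.785 in root. Chromosomes 6A, 6B and 6D part 1 held root runs of 7, 7 and 8 genes, at 234 ± 7.72, 201 ± 3.23 and 373 ± 6.67 TPM in root. There were 67 runs in all, 55 higher in root and 12 higher in leaf, against a shuffled mean of 1.08 and at most 6 (permutation p = 0.001). Genes placed on chromosomes with at least 8-fold change were also mostly higher in root, 3427 against 1706, and the direction of the runs was not tested.

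Of 52089 wheat genes tested, 43031 were called, 29967 higher and 13064 lower in root. A difference of at least 2-fold was found for 26695, 19586 higher and 7109 lower in root, and of at least 8-fold for 5228. With the filter applied again, genes at least 2-fold higher in root numbered 9904 and 9391 without root replicates 1 and 2, and those of at least 8-fold 2869 and 2856. Without leaf replicates 1 and 2, genes at least 2-fold lower in root numbered 4138 and 4135. Quantile normalization gave 12101 higher and 11650 lower at 2-fold. At least 20 TPM in both root libraries was found for 331 genes listed at 0 in both leaf libraries, and the converse for 49. The share of calls higher in root was 69.6% with TPM as deposited, 55.4% with median-ratio scaling and 50.3% with quantile normalization. The median log2 difference of all genes was 0.56 as deposited and 0.14 with median-ratio scaling.

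Wheat leaf and root drew unequally on the chromosomes, while the share of each subgenome differed by less than 1% of TPM between them. Chromosomes 1A, 1B and 1D together held 19.05% ± 0.0921 of TPM in root and 11.1% ± 0.0110 in leaf, and chromosomes 5A, 5B and 5D held 13.9% ± 0.0775 in root and 22.1% ± 0.151 in leaf (n = 2 each). Without the 100 most abundant genes the shares were 14.8% and 10.98% for the first set, and 14.7% and 16.6% for the second. Subgenome A held 33.4% ± 0.0321 of TPM in leaf and 33.1% ± 0.0505 in root, B 32.3% ± 0.0336 and 32.1% ± 0.00836, and D 34.3% ± 0.00151 and 34.8% ± 0.0421. In leaf 13131 ± 32.5, 13150.0 ± 22.6 and 13134 ± 14.1 genes of A, B and D had TPM of at least 1, and in root 15925.5 ± 114, 16115 ± 38.2 and 15973.5 ± 82.7.

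Called genes were 81.9% of those tested on A, 82.4% on B and 83.3% on D. A and D differed in this share (odds ratio 0.910, Fisher's exact test, adjusted p = 0.0054), while A against B (adjusted p = 0.419) and B against D (adjusted p = 0.119) did not pass. The A and D difference was lost among genes of at least 2-fold (odds ratio 0.976, adjusted p = 0.796) and with median-ratio scaling (odds ratio 1.00, adjusted p = 0.956). The share of calls higher in root, 69.4%, 69.9% and 69.7% on A, B and D, passed the test in no pair (adjusted p of 0.527 to 0.728).

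**Figure D4:**
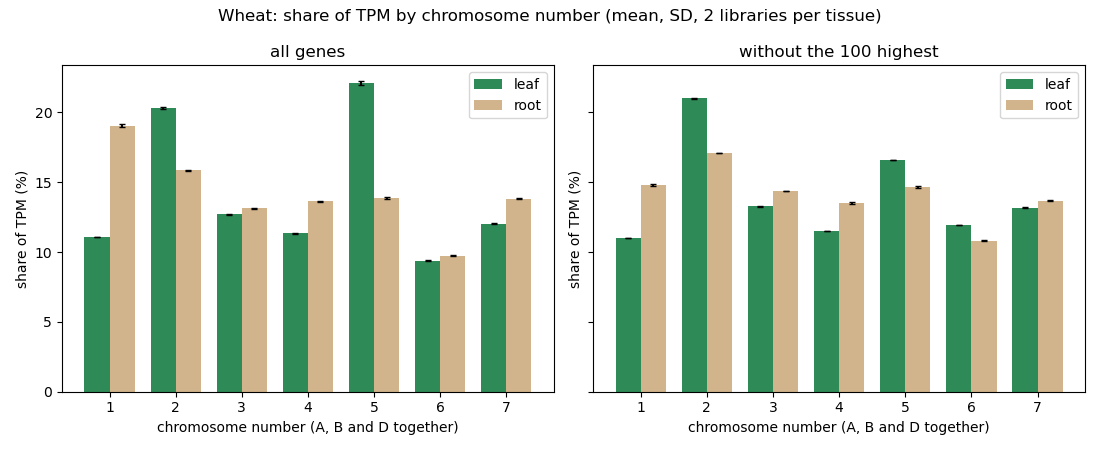
Percent of wheat TPM (y axis) by chromosome number, with A, B and D together (x axis), in leaf and root, over all genes (left) and without the 100 most abundant genes (right). Bars are means with SD of 2 libraries; over all genes the largest gap is chromosome 5, at 22.1% in leaf and 13.9% in root, and without the 100 most abundant it is chromosome 2, at 21.01% and 17.1%.

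Large tissue differences lay towards both chromosome ends in wheat and in root minus leaf and embryo minus root of Ae. tauschii. In wheat, 11.6% of distal and 8.13% of proximal genes were called with at least 8-fold change (odds ratio 1.48, Fisher's exact test, adjusted p = 1.90e-38). In Ae. tauschii the shares were 17.6% and 12.9% for root minus leaf (odds ratio 1.43, adjusted p = 1.26e-22), 16.4% and 14.5% for embryo minus leaf (odds ratio 1.1602, adjusted p = 4.28e-05), and 14.0% and 10.2% for embryo minus root (odds ratio 1.44, adjusted p = 3.54e-19). For embryo minus leaf the share was 18.8% in the first 5% of chromosome length and 15.7% in the last, against 16.6% between 70% and 75%. So the share in the last 5% lay below that of this inner stretch, though above the 14.5% of all proximal genes. The 8-fold shares were not tested within classes of mean TPM. Among calls of any size, distal genes were called more often in wheat (odds ratio 1.12, adjusted p = 9.59e-07) and less often in embryo minus leaf (odds ratio 0.818, adjusted p = 2.00e-08). The latter turned when only the embryo and leaf libraries were fitted (odds ratio 1.19, Fisher's exact test, unadjusted p = 5.37e-05). Within 5 classes of mean TPM it was lost (odds ratio 0.992, adjusted p = 0.835). Root minus leaf (odds ratio 1.05, adjusted p = 0.207) and embryo minus root (odds ratio 1.03, adjusted p = 0.427) did not pass; within 5 classes of mean TPM they passed, at 1.17 (adjusted p = 5.07e-05) and 1.07 (adjusted p = 0.0323).

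**Figure D5:**
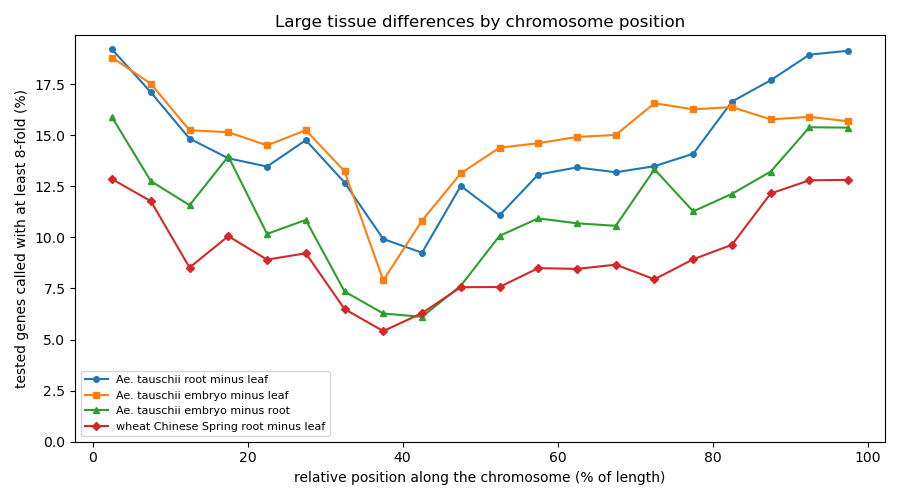
Percent of tested genes called with at least 8-fold change (y axis) by relative position along the chromosome in steps of 5% (x axis), for 3 Ae. tauschii comparisons and wheat. In wheat the share is 12.8% in the first and last step and 5.41% between 35% and 40%.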

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

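Alternatives chosen after the data were seen were those for runs, snoRNA loci and neighbouring rice calls on other fits, those for distal genes at 8-fold, by level and on other fits, subgenome calls on other fits, and the filter applied again when a replicate was left out. Leaving out a replicate kept the genes tested with all libraries, which was also chosen after seeing the data; the lone sample left was assumed to vary like the others. Alternatives for gene lists were not run, because the lists were void.

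The genes named by rule kept direction and call in the 406 cases in which an alternative tested them. With the filter applied again, genes near 0 in a group need TPM 1 in 2 libraries of the other. So the named rice genes were not tested without a replicate of the cultivar that expressed them, nor AET4Gv20012800 and AET1Gv20559900 without a root replicate, nor TraesCS2A02G066700 without a leaf replicate. Counts of called genes stayed within 1.5 times the reported count in 23 alternatives for Ae. tauschii root minus leaf, 23 for embryo minus leaf, 22 for embryo minus root, 17 for rice and 16 for wheat. A minimum 2-fold change left 1827 calls in rice, 10495 in embryo minus root and 26695 in wheat, by its construction, and a filter at TPM 5 left 25615 in wheat, since fewer genes were tested. Without each replicate in turn, calls were 6844 to 7256 in rice, 18562 to 19694 in root minus leaf, 18172 to 18818 in embryo minus leaf, 16043 to 18316 in embryo minus root and 35706 to 38902 in wheat. With the filter applied again they were 7560 to 9032, 16809 to 19544, 17268 to 18777, 14447 to 18400 and 29415 to 37630. With pseudocount 0.1, calls of at least 8-fold were 535 in rice, 6877, 6797 and 5582 in Ae. tauschii and 13119 in wheat, since fold changes of genes with low TPM are larger by construction. FPKM gave 119 in rice. Runs numbered 22 to 24 in rice, 21 to 30, 8 to 10 and 27 to 31 in Ae. tauschii in the order above, and 54 to 71 in wheat.

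Replicate numbers are shared between groups but not shown to pair libraries. The correlation of deviations was 0.0595 in rice, -0.0309, 0.0257 and 0.0149 in Ae. tauschii and -0.00109 in wheat. With the replicate block, calls were 10963 in rice, 20048, 19341 and 18254 in Ae. tauschii and 43261 in wheat.

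Genes at TPM 5 in place of 1 numbered 12197 in rye, 11397.5 in Ae. tauschii leaf, 18902 in wheat leaf and 24831 in wheat root, by construction. On subgenomes A, B and D they numbered 6205.5, 6271 and 6240 in wheat leaf and 8069, 8257 and 8264 in root. Without the 100 most abundant genes the shares of TPM were 32.5%, 33.9% and 33.6% in leaf and 32.1%, 33.4% and 34.5% in root. The difference in calls between A and D was lost with median-ratio scaling, with an odds ratio of 1.00, and at 2-fold, with 0.976; the cause was not tested.

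For distal against proximal calls, 31 alternatives left the result as it was. On other fits the p-values of Fisher's exact test were not adjusted over the comparisons, unlike those of the reported result. For root minus leaf the odds ratio passed at 8-fold (1.43), within 5 classes of mean TPM (1.17), with median-ratio scaling (1.07), and with only 4 libraries (1.19); without each replicate in turn it was 1.06 to 1.11 and passed without either leaf or either root replicate, not without an embryo one. For embryo minus root it passed at 8-fold (1.44), within classes (1.07), and with only 4 libraries (1.13); without each replicate in turn it was 1.03 to 1.10 and passed without either embryo or either root replicate, not without a leaf one. For embryo minus leaf it reversed at 8-fold (1.1602) and with only 4 libraries (1.19), and was lost within classes (0.992). The cause was not tested.

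In the simulated data 66% of 1.25-fold changes were recovered in rice, 0% in Ae. tauschii and 14% in wheat. These values hold only for genes with a mean TPM well above the filter. The effect of depth on recovery was not tested.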

Other observations

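Tests chosen after the result was seen were those of depth, that of a few abundant genes for snoRNA loci, that of direction among rice genes of at least 2-fold, those of rice windows and runs, and camera on noncoding classes.

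Barley seedlings were not part of a comparison. Of 202 nuclear barley genes with names, 137 had TPM of at least 1 and 36 at least 100. The 5 genes with the highest TPM had no names, so the most abundant named genes are given, chosen after their values were seen. PsaD, a photosystem I subunit, was at 2336 ± 20.4 TPM (SD, n = 2; chromosome 5H part 2, 230712092 to 230713548) and Psak at 2263 ± 44.3 (2H part 2, 3885878 to 3887371). Methyljasmonate-inducible lipoxygenase 2 was at 2038 ± 57.3 TPM (5H part 1, 3924122 to 3928957), Ha1 at 1357 ± 21.8 (2H part 2, 323652502 to 323658875) and GS1a at 886 ± 4.40 (6H part 2, 112158867 to 112163479). In maize seedlings the 154 listed microRNA precursors summed to 300.3 ± 10.7 TPM, and a mean of 29 of them had TPM of at least 1.

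Of the patterns weighed, the first is the lower level of snoRNA loci in Ae. tauschii leaf than in root. The class did not pass against other genes (camera adjusted p = 0.155, or 0.497 with an estimated correlation), and the median log2 difference of all tested genes was 0.78. Reads of overlapping listed genes are argued against by the 95 loci that overlap no other listed gene, with a median log2 difference of 1.32. Reads of transcripts outside the listed genes cannot be judged this way. Libraries of a tissue differed by at most 1.12-fold in summed snoRNA TPM despite unequal depth, against 4.40-fold between root and leaf, and without the 100 most abundant genes of each library the ratio was 3.12. A difference between the tissues, carry-over of RNA without poly(A) tails and library differences between tissues stay open and were not tested.

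More genes passed TPM 1 in root than in leaf in Ae. tauschii and wheat. Abundant leaf genes lower the TPM of all others, but without the 100 most abundant genes 74.2% of the difference was left in Ae. tauschii and 79.9% in wheat, so they may explain a part and not the whole. Libraries of a tissue differed by at most 324 genes, against differences of 3379.5 and 8701 between tissues. With median-ratio scaling the differences were 1881.5 and 4213.5. A greater range of cell types in root stays open and was not tested.

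Rice cultivar differences clustered along chromosomes. Overlapping genes are argued against by neighbours that do not overlap, with both called in 24.1% of pairs, above the 23.3% that shuffles reached. If ZH11 alleles aligned less well to the reference, clustered calls would be lower in ZH11 more often than others. Over all calls this was not seen (odds ratio 0.980, Fisher's exact p = 0.678), while among genes of at least 2-fold 46.8% of 698 with such a neighbour were lower in ZH11, against 29.2% of 1127 without (odds ratio 2.14, Fisher's exact p = 4.04e-14). Of 23 windows with an excess 20 were mostly lower in ZH11, as were 17 of 24 runs, so divergent or missing ZH11 sequence may add to the clustering of large differences; which cultivar lies closer to the reference is unknown, and cultivar differences in gene regulation stay open and were not tested.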
